A study of Mus musculus with 24 samples.

How the data were processed

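RNA was measured in whole liver of 24 mice, 12 females and 12 males, after 3 weeks on the Lieber-DeCarli liquid alcohol diet. Per the labels, the mice had received adeno-associated virus (AAV) vectors that express short hairpin RNAs. The first injection carried either a control hairpin or a pair of vectors against Kdm5b and Kdm5c, which encode histone H3 lysine demethylases. The second carried a control hairpin or a vector against Ahr, the aryl hydrocarbon receptor. Crossing the injections with sex gives 8 groups of 3 mice, and each library came from its own mouse. Groups were taken from the labels alone, and replicates were numbered 1 to 3 within a group in the order of the samples, so that the numbers pair nothing. The labels give no batch, cage, or collection time.

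The deposited table gives 1 value per gene and library as FPKM (fragments mapped to a gene, scaled by transcript length and by the mapped fragments of the library), per the file headers, rounded by the authors to 2 decimals. The name under which the table was deposited speaks of raw counts, but every measured column is headed and scaled as FPKM. Per the submitters' processing notes, HISAT and Bowtie2 were used with the mouse build GRCm38.p6; their versions and the counting step are not given in the sources used here. Libraries were made with standard protocols of the sequencing provider, per the labels' protocols, and no statement on strand is given there, so overlapping and antisense genes cannot be separated. The table as used here holds 2372 genes, of which 2360 are marked as mRNA. How these genes were chosen is not stated. Its rows run almost in order of an equal-variance comparison of the female Kdm5 vectors with the female control vectors computed on FPKM, with 99.9% of neighbouring rows ascending. That order runs from small to large p, and 15.3% of the genes lie under 0.05.

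Read depth is unknown, because FPKM removes it. The low values lie near the rounding step of 0.01, so whole reads could not be recovered, and no counting interval is given. The FPKM of the 2372 genes sum to between 281871 and 326460 in female libraries and between 380206 and 429780 in male libraries. These sums are not depths. The 19 Mup genes in the table, which encode major urinary proteins, take 14.0% to 25.7% of the sum in males and 2.26% to 5.93% in females. No pair of libraries held identical values.

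A count model had been fixed before the data were examined and could not be used on FPKM. It was replaced by limma 3.58.1 in R 4.3.3. Values were tested as log2(FPKM + 0.5) in all 24 libraries with 1 mean per group, an intensity trend, and robust moderation of the variance. Genes with at least 1 FPKM in at least 3 libraries were tested, which kept 2299 and left out 73. Fold changes are on this log2(FPKM + 0.5) scale, which understates the change of low genes. Adjusted p-values are Benjamini-Hochberg values from limma over the 2299 genes, with a threshold of 0.05. Since the genes of the table are a chosen part of the transcriptome, an adjusted p holds within this table only. A ± after a log2 fold change is its standard error, and a ± after an FPKM value is the SD of 3 mice. The test fits 16 residual degrees of freedom over the 8 groups, so that each comparison borrows its spread from all libraries.

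The 15 comparisons were fixed before the data were examined: the Kdm5 vectors and the AhR vector each against control vectors in each sex, each added to the other, both together, the difference of effects between the sexes, the interaction of both vectors, and females against males with control vectors. The same holds for 34 gene lists, of which 22 had the 5 tested members needed for a test. Of 566 listed members, 245 were in the table. Lists were tested with camera at a preset correlation of 0.01 and again with an estimated correlation, with adjustment over the lists of each comparison. The genes named were chosen by a rule. It takes Kdm5b, Kdm5c and Ahr always, then up to 10 highest and 10 lowest log2 fold changes among genes that passed, had a mean of at least 1 FPKM in the compared libraries (a CPM minimum in the rule as written), and did not overlap between 2 compared groups. It adds up to 4 members of each list that passed. Kdm5b and Ahr were not analysed here, and some other genes that the rule takes are not reported here.

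The procedure was tested on simulated data. With 200 of the 2299 genes changed in the female Kdm5 comparison, 62% of those changed by 0.5 log2 and 92% of those changed by 1 log2 were recovered, and 4.94% of calls were false. In the male comparison, 39% and 89% were recovered, and 5.88% of calls were false. Simulated genes varied independently of each other, with the same spread in all groups, as the test assumes. These shares may therefore be too favourable for the real libraries. Alternatives tried were another scaling (median of ratios), no filter, a stricter filter, other pseudocounts, library weights, fits on the compared groups alone, averages over both settings of the other vector, a clock gene covariate, and each library left out in turn. Gene positions are from the RefSeq annotation of GRCm38.p6, in which 2358 of the 2372 gene identifiers were found. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.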

Results

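Liver RNA of 24 alcohol-fed mice was compared across 8 groups of 3, formed by sex, by hairpin vectors against Kdm5b and Kdm5c (the Kdm5 vectors), and by a hairpin vector against Ahr (the AhR vector). The study asks whether these demethylases act differently in the 2 sexes when the liver is injured by alcohol, so each vector effect was measured in females and in males and the effects were then compared. Sex was the main axis of the data, with 73.6% of the variance on the first principal component. The Y-linked genes Ddx3y, Uty, Kdm5d and Eif2s3y separated the sexes in all 24 libraries. Ddx3y, for example, lay at or below 0.26 FPKM in females and at or above 8.67 FPKM in males.

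**Figure D1:**
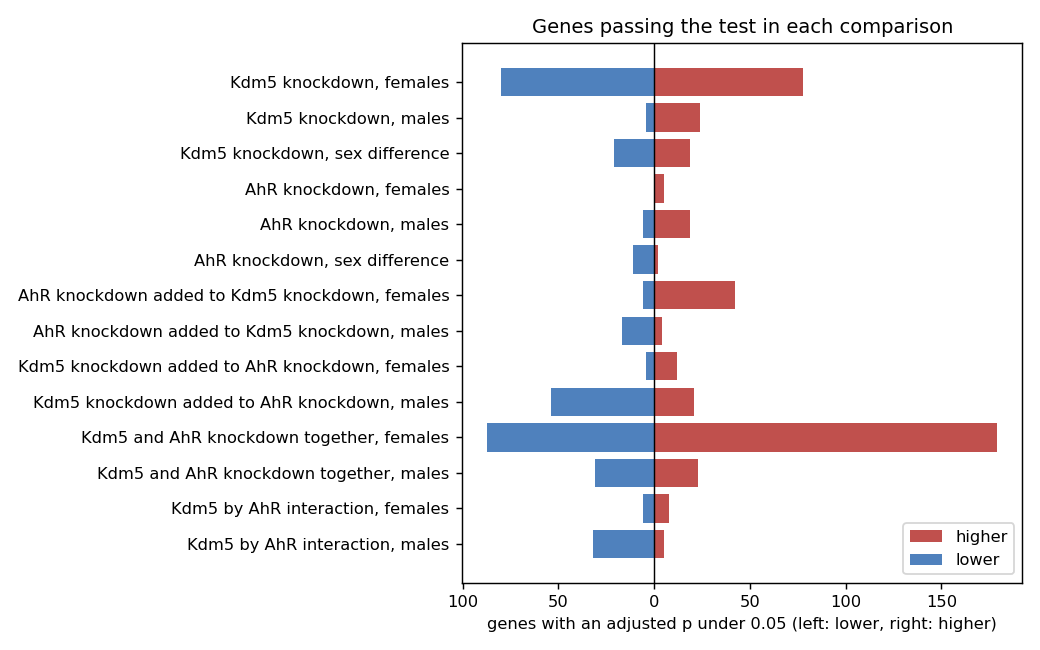
Number of genes with an adjusted p under 0.05 in each vector comparison, out of 2299 tested, with genes that were higher to the right and genes that were lower to the left. The longest bars are those of both vectors together in females, with 179 higher and 87 lower.

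Of the targeted genes, Kdm5c (chromosome X, 152233198 to 152279102 of GRCm38.p6) could be followed. In males it stood at 6.80 ± 0.41 FPKM with control vectors and 5.14 ± 0.661 FPKM with the Kdm5 vectors, a log2 fold change of -0.38 ± 0.11 that did not pass (adjusted p = 0.14). In males that also received the AhR vector, Kdm5c fell from 7.47 ± 0.483 to 5.11 ± 0.25 FPKM, a log2 fold change of -0.51 ± 0.11 (adjusted p = 0.0124). In females it measured 10.3 ± 0.906 FPKM with control vectors and 9.63 ± 0.503 FPKM with the Kdm5 vectors. The female log2 fold change of -0.09 ± 0.11 has a 95% confidence interval from -0.32 to 0.14, and its adjusted p was 0.66. Averaged over both settings of the AhR vector, the male change was -0.44 (adjusted p = 0.00215) and the female change -0.17 (adjusted p = 0.169), and the difference between them did not pass (adjusted p = 0.144). With control vectors Kdm5c was higher in females than in males by 0.57 ± 0.11 on the log2 scale (adjusted p = 0.00037). Kdm5b and Ahr were not analysed here. Of the AhR target genes, Cyp1a2 changed by -0.01 log2 in females and -0.08 in males under the AhR vector, with adjusted p of 0.99 and 0.93, so that the effect of that vector on its target is not checked by these values.

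**Figure D2:**
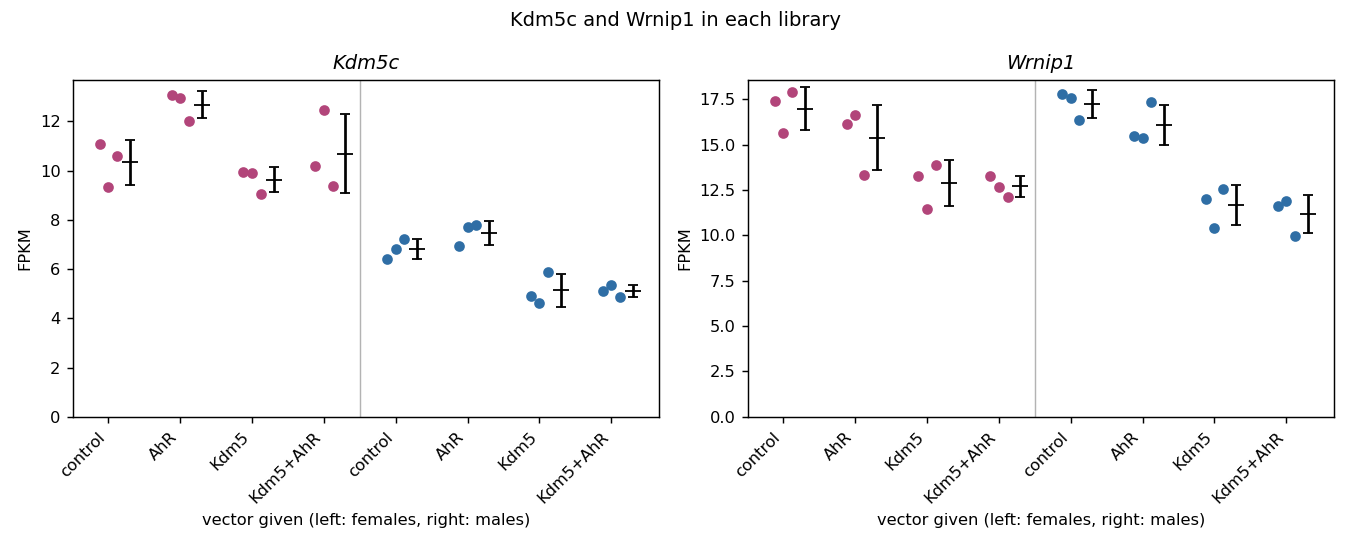
FPKM of Kdm5c and Wrnip1 in each library (points) by vector, females at the left of each panel and males at the right, with the mean and SD of 3 mice beside them. Male Kdm5c averages 5.14 and 5.11 FPKM in the groups given the Kdm5 vectors against 6.80 and 7.47 FPKM without them, and Wrnip1 averages 11.2 to 12.9 FPKM with them in both sexes.

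In females, the Kdm5 vectors raised Afp, Cyp7a1 and Cyp8b1 and lowered Abcb11 and several cytochrome P450 genes. Afp, the fetal serum protein alpha-fetoprotein (chromosome 5, 90490714 to 90508907), rose from 0.203 ± 0.142 to 8.22 ± 2.22 FPKM, a log2 fold change of 3.62 ± 0.29 (adjusted p = 1.6e-07). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, rose 5.56-fold and Cyp8b1, the sterol 12-alpha-hydroxylase of the same pathway, rose 3.12-fold, with control libraries that spread widely (142 ± 126 FPKM for Cyp8b1). Abcb11, the bile salt export pump, fell 1.79-fold. In all, 158 of 2299 genes passed, 78 higher and 80 lower.

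Among the other genes that rose in these females were the insulin receptor substrate Irs2 (2.28-fold), the tubulin gene Tuba8 (2.35-fold), the hepatocyte transcription factor Onecut1 (1.92-fold), the phosphate carrier Slc34a2 (2.09-fold), Paqr9 (1.91-fold), Tlr12 (1.90-fold) and Gpr137 (1.87-fold). The genes that fell most were Cox7a1, a subunit of cytochrome c oxidase (3.55-fold), the cytochrome P450 genes Cyp3a44 (3.21-fold), Cyp2c70 (3.01-fold) and Cyp2c69 (2.91-fold), and the NADPH oxidase gene Nox4 (2.30-fold). Nat8f1 fell 2.28-fold, Ptgds 2.27-fold, Rnf125 2.17-fold, Cables1 1.98-fold, the splicing factor gene Srsf5 1.97-fold and Eepd1 1.96-fold. Reads of the Cyp3a and Cyp2c families can be shared between close copies, so single members of these families are uncertain.

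Of 22 tested genes of PPAR alpha and fatty acid oxidation, 3 rose in females given the Kdm5 vectors and none fell; 11 passed when adjusted over the list alone, 10 of them higher. Cpt2 rose by 0.47 and Hadha by 0.31 on the log2 scale. The list as a whole was higher with the preset correlation (adjusted p = 0.00492), but not with an estimated correlation (adjusted p = 0.99). All 7 tested genes of cholesterol synthesis had log2 fold changes below 0; the list was lower at the preset correlation (adjusted p = 0.0262), again not with an estimated correlation (adjusted p = 0.99). Lss was the member that passed, at -0.78 ± 0.22, and 3 members passed when adjusted over the list alone. Of 15 bile acid genes, 3 passed, 2 higher and 1 lower, and 5 passed when adjusted over the list alone; the list did not pass (adjusted p = 0.98). Of 22 female-biased liver genes, Cyp3a44, Cyp2c69 and the transporter gene Slc22a26 fell and none rose. The pericentral gene Lhpp rose 1.64-fold and the pericentral gene Rgn fell 1.82-fold. Among markers of sinusoidal endothelium, Lyve1 and Gpr182 rose by 0.75 and 0.62 log2, while the 8 tested markers as a list did not pass (adjusted p = 0.67). Single members that fell in other lists were Fads1 (1.38-fold), the acute phase gene Crp (1.45-fold), the interferon-induced gene Ifi47 (1.54-fold) and the lysosomal protease gene Ctsc (1.63-fold).

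The female Kdm5 count depended on the libraries used. Without control mice 1, 2 and 3 it was 23, 279 and 106, and without Kdm5 mice 1, 2 and 3 it was 86, 74 and 100. Of 35 genes taken by the rule 7 passed in each of these 6 fits, namely Afp, Tuba8, Gpr137, Cyp3a44, Nat8f1, Srsf5 and Rgn. Cyp7a1 failed in 5 of them, all but that without control mouse 2, with log2 changes from 1.76 to 3.23, and Cyp8b1 failed without control mouse 1 or 3, with a range from 1.14 to 2.33. Fitted on these 6 libraries alone, 1 gene passed and 422 had an unadjusted p under 0.05.

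In males that received no AhR vector, the Kdm5 vectors raised 24 genes and lowered 4 of 2299. Lpin1, a phosphatidate phosphatase of triglyceride synthesis (chromosome 12, 16535669 to 16653903), rose from 9.89 ± 5.22 to 59.3 ± 8.52 FPKM, 6.30-fold, with a log2 fold change of 2.65 ± 0.50 (adjusted p = 0.011). The transcription factor Zbtb16 rose 6.14-fold and the clock repressor Ciart 5.24-fold. The cytokine receptor genes Il1r1 and Il6ra rose 3.34-fold and 1.91-fold. Fitted on these 6 libraries alone 19 genes passed, all 19 higher, and averaged over both settings of the AhR vector 51 passed, 26 higher and 25 lower.

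Other genes that rose in these males were Arhgef26 (2.47-fold), Rhobtb1 (2.25-fold), Fam214a (2.08-fold), Mtss1 (1.97-fold) and Herpud1, a gene of endoplasmic reticulum stress (1.88-fold). The 4 that fell were Ugt2b38, a glucuronosyltransferase (2.59-fold), the mitochondrial carrier Slc25a30 (1.93-fold), Wrnip1 (1.46-fold) and Pnrc1 (1.30-fold). Wrnip1, which encodes an ATPase that binds the Werner helicase (chromosome 13, 32802030 to 32822610), fell from 17.2 ± 0.776 to 11.7 ± 1.12 FPKM. Of 13 clock genes, 11 had log2 fold changes above 0, Ciart passed, and 4 passed when adjusted over the list alone. As a list they were higher (adjusted p = 0.00326), with an adjusted p = 0.083 at an estimated correlation. The 9 macrophage and Kupffer cell markers all lay below 0 with a median of -0.27 and none passed alone; the list was lower at the preset correlation (adjusted p = 0.00326) but not with an estimated correlation (adjusted p = 0.84). Clec4f and C1qa, for example, stood at -0.22 and -0.27. The 18 male-biased liver genes had a median of -0.24, none passed alone, and the list was lower (adjusted p = 0.0207; adjusted p = 0.84 with an estimated correlation). Without control mice 1, 2 and 3 the male count was 1, 14 and 9, and without Kdm5 mice 1, 2 and 3 it was 0 (194 at an unadjusted p under 0.05 in limma), 11 and 14. None of 14 genes taken by the rule passed in each of these 6 fits: Zbtb16 and Ciart failed in all 6, with log2 changes from 2.17 to 2.96 and from 2.26 to 2.50, Il6ra in 5, and Lpin1 and Il1r1 in 2, those without control mouse 1 and Kdm5 mouse 1. With a clock gene score as covariate 0 genes passed in limma, with 203 at an unadjusted p under 0.05.

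The effects of the Kdm5 vectors in females and in males were then compared with each other. Afp differed by 3.03 ± 0.41 log2 in favour of females (adjusted p = 0.00087), and Lpin1 by -3.66 ± 0.71 (adjusted p = 0.021), meaning a higher effect in males. In total 40 genes differed, 19 with the higher effect in females and 21 with the higher effect in males. The first kind included Tuba8, Irs2, Onecut1, Paqr9, Gpr137 and the heat shock gene Hspa1b, with differences from 1.18 to 2.08. The second included Il1r1, Cyp3a44, Ppargc1a, a coactivator of mitochondrial genes, Herpud1, the amino acid transporter Slc38a2, and Rgn, with differences from -2.13 to -0.94. Higher is meant with its sign, here and for the AhR vector below. Cyp3a44 and Rgn both fell in females, Cyp3a44 with a log2 change of -1.68 against a difference of -1.75. A negative difference therefore need not mean a larger change in males. The 22 genes of PPAR alpha and fatty acid oxidation had a higher effect in females as a list (adjusted p = 0.00717; adjusted p = 0.83 with an estimated correlation). Without female control mice 1, 2 and 3 the count was 1, 63 and 30, without female Kdm5 mice 24, 13 and 22, without male control mice 67, 26 and 2, and without male Kdm5 mice 7, 32 and 2. Afp alone of 21 genes taken by the rule passed in each of these 12 fits. Ppp2r5e and Fam214a rose and Wrnip1 fell in both sexes, chosen here after their values were seen. By chance 0.814 shared higher genes and 0.139 shared lower genes would arise from lists of these sizes. The overlaps were no clear excess, with one-sided Fisher's exact p of 0.195 and 0.132, which treat genes as independent. Across the 2299 genes, which are not independent replicates, the female and male log2 fold changes had Pearson's r = 0.04 and Spearman's rho = 0.03, with exact permutation p of 0.76 and 0.72 over 100 relabelings (adjusted p = 0.90 and 0.86 over 6 correlations). Within females, the effects of the Kdm5 vectors with and without the AhR vector had r = 0.38 and rho = 0.35 (exact permutation p = 0.04 and 0.05; adjusted p = 0.24 and 0.30). Within males they had r = 0.16 and rho = 0.12 (exact permutation p = 0.28 and 0.38; adjusted p = 0.56 and 0.57).

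In females the AhR vector raised 5 genes and lowered none. Afp rose from 0.203 ± 0.142 to 15.8 ± 5.23 FPKM, 22.6-fold, with a log2 fold change of 4.50 ± 0.29 (adjusted p = 3.1e-09). Ppp2r5e, a regulatory subunit of protein phosphatase 2A, rose 1.62-fold, Erc1 1.42-fold, and Mavs, the mitochondrial adaptor of antiviral signalling, 1.41-fold. The fifth was the fetal growth factor gene Igf2, at 1.08 ± 0.16 log2 (adjusted p = 0.00204), which lay between 0.55 and 1.17 FPKM in the 9 females given an active vector and was chosen after its values were seen. All 5 were also higher under the Kdm5 vectors in females, where both comparisons use the same control mice. Lists of 78 and 5 genes would share 0.17 by chance, and unchanged groups simulated against shared controls shared at most 1 call. That simulation sets no firm bound, since its genes varied independently. Other splits of the real libraries gave up to 90 calls for the Kdm5 vectors and 19 for the AhR vector in females. The fold changes of both comparisons had r = 0.54 against a simulated 0.50, and a covariance of 0.0532 against a simulated 0.021. The 3 controls cannot be split, so part of the excess may come from them. With another scaling 9 genes passed, 8 higher and 1 lower. The stricter filter leaves out low genes, among them Afp and Igf2, which were therefore not tested with it. Of the other genes named here, 1 passed with that filter. Without control mice 1, 2 and 3 the count was 3, 3 and 11, and without AhR mice 1, 2 and 3 it was 12, 4 and 3, with Afp alone of 4 genes taken by the rule passing in each fit.

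**Figure D3:**
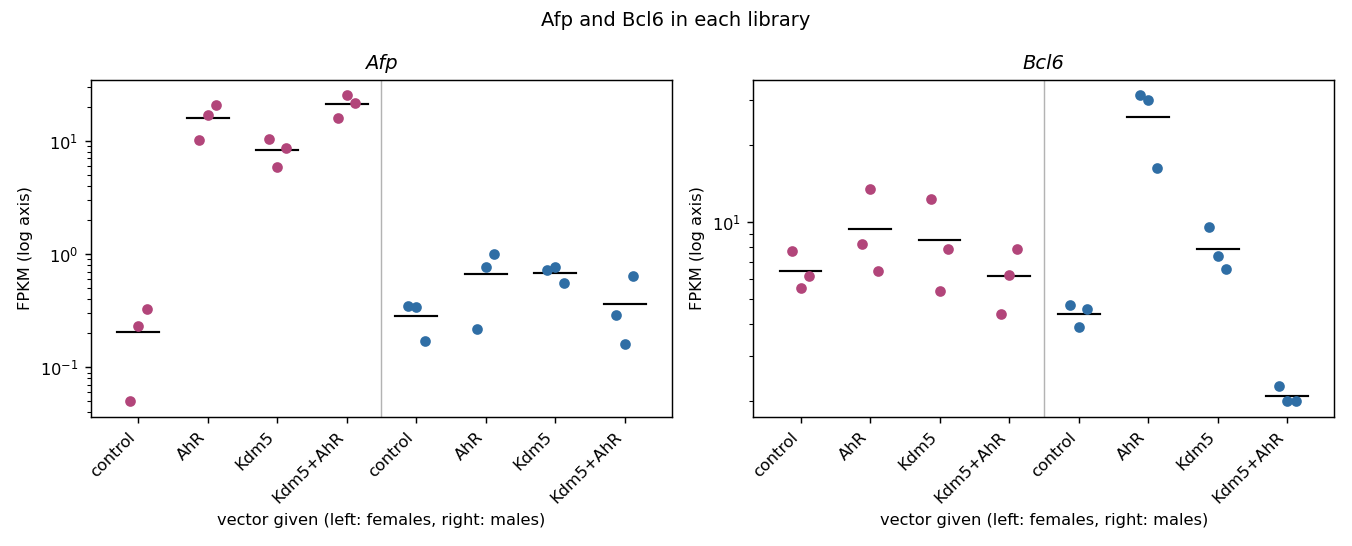
FPKM of Afp and Bcl6 in each library (points; log axis) by vector, females at the left and males at the right of each panel, with a line at the mean of 3 mice. Afp lies between 5.85 and 25.2 FPKM in the 9 females given an active vector and at or below 1.01 FPKM in the other 15 libraries, and Bcl6 averages 25.9 FPKM in males given the AhR vector alone.

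In males the AhR vector raised the transcriptional repressor Bcl6 (chromosome 16, 23965050 to 23988866) from 4.39 ± 0.444 to 25.9 ± 8.36 FPKM, with a log2 fold change of 2.38 ± 0.29 (adjusted p = 0.00011). H2-Ab1 rose 2.27-fold, H2-Aa 2.22-fold and Cd74 1.94-fold, all of them genes of antigen presentation by MHC class II. Cyp2b10, a cytochrome P450 induced by foreign compounds, fell 5.01-fold. In all 25 genes passed, 19 higher and 6 lower.

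Also higher in these males were Arrdc2 (2.49-fold), the kinase Pim3 (2.32-fold), Herpud1 (2.30-fold), Tcim (2.23-fold), Spata2l (2.00-fold), the interferon-induced Gbp2 (2.02-fold) and the clock gene Per1 (1.90-fold). Lower were Cyp26b1, which degrades retinoic acid (1.92-fold), the clock activator Arntl (1.80-fold), the sulfotransferase Sult1d1 (1.74-fold), Acacb, an acetyl-CoA carboxylase (1.49-fold), and Abcd4 (1.45-fold). All 7 interferon-stimulated genes lay above 0, 1 passed, and 5 passed when adjusted over the list alone. The list was higher at the preset correlation (adjusted p = 5.7e-05) but not with an estimated correlation (adjusted p = 0.57). With another scaling 11 genes were higher and 9 lower. Without control mice 1, 2 and 3 the count was 26, 22 and 14, without AhR mice 1, 2 and 3 it was 15, 19 and 9, and with the clock covariate it was 2. Bcl6, H2-Ab1, Arrdc2, Herpud1 and Spata2l, 5 of 17 genes taken by the rule, passed in each fit without 1 library, while Cyp2b10 failed in 4 of 6.

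The effect of the AhR vector differed between the sexes for 13 genes, 2 with a higher effect in females and 11 with a higher effect in males; with another scaling the split was 5 and 6. Afp had the higher effect in females, by 3.99 ± 0.41 log2 (adjusted p = 1.1e-05), as had Igf2, by 1.27 ± 0.23, which was chosen after its values were seen. Bcl6 (-1.92 ± 0.41), Arrdc2, H2-Aa, H2-Ab1, Cd74, Spata2l, Herpud1, Rasgef1b and the potassium channel gene Kcnk5 had the higher effect in males. Across genes the female and male changes had r = -0.02 and rho = -0.02 (exact permutation p = 0.90 and 0.88; adjusted p = 0.90 and 0.88). The count was 4 without female control mouse 1 or female AhR mouse 1, 5 without male control mouse 1, and 6 without male AhR mouse 3. Afp and Spata2l, 2 of 11 genes taken by the rule, passed in each of 12 fits without 1 library, and Bcl6 failed in 8.

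Given together, both sets of vectors changed 266 genes in females, 179 higher and 87 lower. Afp rose to 20.9 ± 4.61 FPKM, a log2 fold change of 4.92 ± 0.29 (adjusted p = 5.9e-10). The sulfotransferase genes Sult2a3, Sult2a1 and Sult2a5 rose 7.37-fold, 6.92-fold and 4.05-fold. The clock output genes Dbp and Tef rose 4.73-fold and 2.08-fold, and the clock repressors Nr1d1 and Per3 rose 3.87-fold and 2.36-fold, while Cry1 fell 2.02-fold. The organic anion transporter Slco1a1 fell 4.78-fold.

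Of 13 clock genes, 7 passed in these females, 4 higher and 3 lower, and 8 passed when adjusted over the list alone; the lower ones were Cry1, Nfil3 at -0.77 and Arntl at -0.55. Of 22 genes of PPAR alpha and fatty acid oxidation, 3 rose, among them Cpt1a (1.60-fold) and Hadha (1.29-fold), and 4 when adjusted over the list alone; the list did not pass (adjusted p = 0.12). Of 7 genes of stellate cell activation and matrix, Postn, Pdgfra and Fn1 rose, by 0.55, 0.42 and 0.41 log2. Of 7 quiescent stellate cell markers Dcn alone passed (1.31-fold), and of 9 macrophage markers Cd163 alone (1.61-fold). None of these 3 lists passed, with adjusted p of 0.12, 0.16 and 0.79. Aqp4, Cntnap1, Cgref1, Apob, Ddx58, Gpr182, Slc10a1 and Cyp2b13 also rose. Among genes that fell were Cyp3a44 (2.91-fold), Sult5a1 (2.58-fold), Nat8f1 (2.51-fold), Cyp2c70 (2.45-fold), Rnf125 (2.23-fold), Ces2c (2.19-fold), Mup16 (2.16-fold) and Ces3b (2.01-fold). Rgn, Crp, Cyp2f2 and Fads1 fell by 1.63-fold, 1.48-fold, 1.43-fold and 1.36-fold. Sult2a, Ces and Mup genes have close copies that may share reads. Without control mice 1, 2 and 3 the count was 44, 235 and 238, and without mice 1, 2 and 3 given both it was 140, 105 and 77. Of 39 genes taken by the rule 8 passed in each of these 6 fits, among them Afp, Sult2a3, Dbp and Tef, while Slco1a1 and Sult2a5 failed in 5. Fitted on these 6 libraries alone it was 21, and with the clock covariate 9.

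Given together in males, the vectors raised Ciart 5.53-fold, Lpin1 4.71-fold, Dbp 4.51-fold and Upp2, a uridine phosphorylase, 4.04-fold. Arntl fell 2.10-fold, the linker histone gene Hist1h1c 2.42-fold, and the fatty acid synthase gene Fasn 1.76-fold. In all 54 genes passed, 23 higher and 31 lower. Usp2, Il1r1, Phlda1, Scara5, Mtss1 and Rhobtb1 rose between 2.09-fold and 2.49-fold, Gbp2 rose 1.91-fold and the hepatocyte factor Hnf4a 1.46-fold. Rnf125, Extl1, Asap2, Abtb2, Dtx4, Rfx4, Dapk2 and Tbc1d30 fell between 1.77-fold and 2.15-fold, and Acacb fell by 0.58 on the log2 scale. Of 10 genes of fatty acid and triglyceride synthesis, 1 rose and 2 fell, and 4 passed when adjusted over the list alone. Of 13 clock genes 4 passed, 3 higher and 1 lower, and 8 when adjusted over the list alone. The 7 interferon-stimulated genes were higher as a list (adjusted p = 0.0124; adjusted p = 0.65 with an estimated correlation). Without control mice 1, 2 and 3 the count was 42, 27 and 16, without mice 1, 2 and 3 given both it was 26, 22 and 20 (6 of 24 genes taken by the rule passed in each of these 6 fits, among them Arntl, while Ciart and Lpin1 failed in 5 and Upp2, Hist1h1c and Fasn in all 6), and with the clock covariate it was 0 in limma, with 213 at an unadjusted p under 0.05.

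**Figure D4:**
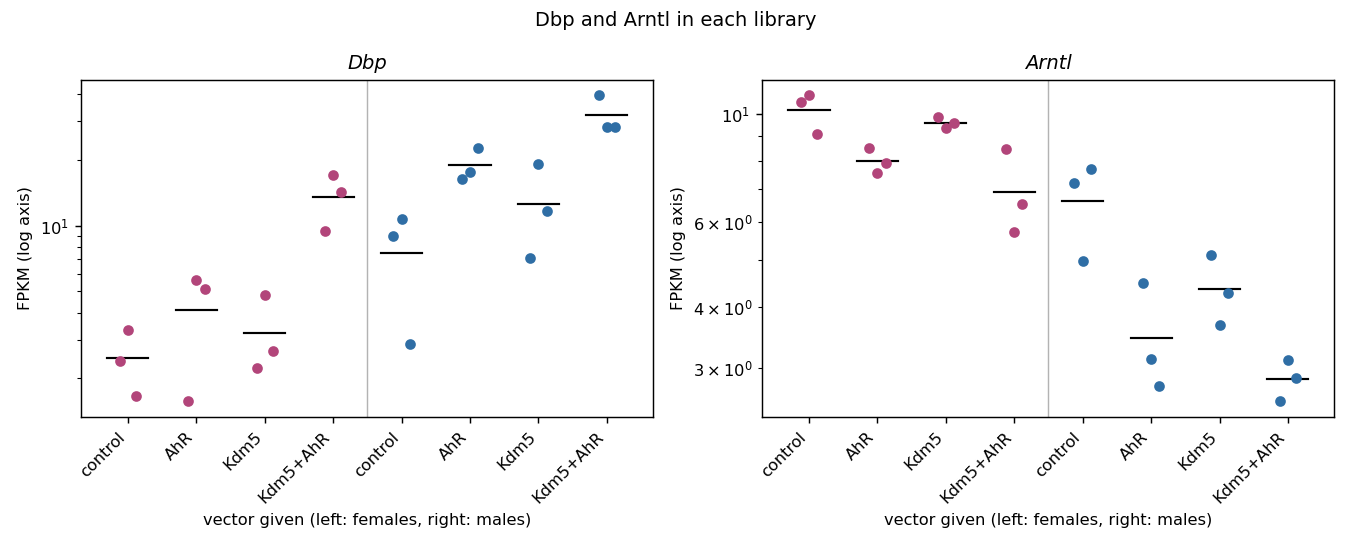
FPKM of the clock genes Dbp and Arntl in each library (points; log axis) by vector, females at the left and males at the right of each panel, with a line at the mean of 3 mice. Mean Dbp is 13.6 FPKM in females and 32.0 FPKM in males given both sets of vectors, against 2.47 and 7.53 FPKM with control vectors.

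Adding the Kdm5 vectors to the AhR vector in males lowered Bcl6, Pim3 and Spata2l, which the AhR vector alone had raised. Bcl6 fell 9.80-fold, from 25.9 ± 8.36 to 2.09 ± 0.165 FPKM (log2 fold change -3.29 ± 0.29, adjusted p = 7.9e-07). Pim3 fell 2.48-fold and Spata2l 2.26-fold. Scara5, a scavenger receptor gene, rose 3.40-fold and Camk2b, a calmodulin-dependent kinase gene, 3.38-fold. In all 75 genes passed, 21 higher and 54 lower; with another scaling the split was 22 and 31. The small GTPase gene Arl4d (3.78-fold), the stress genes Gadd45g (3.69-fold) and Ddit4 (3.56-fold), Irf2bp2 (2.52-fold), Lgals4 (2.23-fold), Rasgef1b (2.22-fold) and Tsc22d3 (2.17-fold) fell, as did Zfp36 (1.95-fold), Per1 (1.76-fold), Nfkbia (1.67-fold) and, by 0.59 on the log2 scale, Acaca. Angptl8, Phlda1, the metallothionein gene Mt1, Fkbp5, Id2, Sowahc, Map3k5 and Nab2 rose between 1.72-fold and 2.44-fold. The 11 acute phase genes were higher as a list (adjusted p = 0.0244; adjusted p = 0.37 with an estimated correlation), with none that passed alone; Orm1 and Lcn2 stood at 0.26 and 0.61. Without AhR mice 1, 2 and 3 the count was 65, 42 and 56, and without mice 1, 2 and 3 given both it was 58, 43 and 35, with 11 of 25 genes taken by the rule, such as Bcl6, Pim3, Spata2l, Scara5 and Camk2b, passing in each fit. Fitted on these 6 libraries alone it was 24.

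The same addition in females changed 16 genes, 12 higher and 4 lower. Fam47e, Gpr146, Spata2l, Nab2, Exoc4, Sphk2, Rsph4a, the glucose transporter gene Slc2a2 and Dglucy rose by 0.57 to 0.95 log2. Cyp3a44 fell by 1.32, the clock gene Nfil3 by 0.95, Hist2h2aa1 by 0.64 and Mapre3 by 0.51 on the log2 scale. The male-biased and the female-biased liver genes were both lower as lists (adjusted p = 0.0288 and 0.0340; adjusted p = 0.52 and 0.47 with an estimated correlation). Without AhR mice 1, 2 and 3 the count was 11, 6 and 36, and without mice 1, 2 and 3 given both it was 7, 7 and 5, with Gpr146 and Spata2l, 2 of 14 genes taken by the rule, passing in each fit. In limma it was 0 on these 6 libraries alone (292 at an unadjusted p under 0.05) and 0 with the clock covariate (246).

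Adding the AhR vector to the Kdm5 vectors in females raised 42 genes and lowered 6. Cox7a1 rose by 2.36 ± 0.49 log2, Dbp by 1.94 ± 0.44, Per3 by 1.35, Afp by 1.30 and Nr1d2 by 1.00. Hacd4, the drug efflux pump gene Abcb1a, Lmbrd2, Rap1gap and Apob rose by 0.48 to 1.10. Nfil3 fell by 1.08, Tuba8 by 0.91, Ccnf by 0.79, Pam16 by 0.62 and Pnrc1 by 0.53. Of 13 clock genes 5 passed, 4 higher and 1 lower, and 8 when adjusted over the list alone. The male-biased list was lower (adjusted p = 0.0247; adjusted p = 0.71 with an estimated correlation). Without Kdm5 mice 1, 2 and 3 the count was 95, 34 and 1, and without mice 1, 2 and 3 given both it was 32, 4 and 0 (373 at an unadjusted p under 0.05), with none of 17 genes taken by the rule passing in each fit. In limma it was 0 on these 6 libraries alone (438 at an unadjusted p under 0.05) and 0 with the clock covariate (251).

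The same addition in males changed 21 genes, 4 higher and 17 lower. Hsd17b6 (1.23 ± 0.27 log2), Phlda1, Onecut1 and H2-Ab1 rose. Bcl6 fell by 1.67, the transporter gene Slc45a3 by 1.01, Lgals4 and Morc4 by 0.97, Celsr1 by 0.92, Sult1d1 by 0.91, Prob1 by 0.81, Cyp39a1 by 0.79, Spata2l by 0.73, Etv6 by 0.69 and Acacb by 0.66. Acacb and Sult1d1 fell and H2-Ab1 rose under the AhR vector with and without the Kdm5 vectors. However, Acacb failed in all 6 fits without 1 library in both comparisons. H2-Ab1 failed in 5 of 6 with the Kdm5 vectors and passed in all 6 without them. The fold changes of the AhR vector with and without the Kdm5 vectors had r = 0.09 and rho = 0.18 in males (exact permutation p = 0.42 and 0.15; adjusted p = 0.63 and 0.42). In females they had r = 0.21 and rho = 0.21 (exact permutation p = 0.20 and 0.21; adjusted p = 0.56 and 0.42). Without Kdm5 mice 1, 2 and 3 the male count was 0 (282 at an unadjusted p under 0.05 in limma), 9 and 3, and without mice 1, 2 and 3 given both it was 14, 5 and 0 (311), with none of 15 genes taken by the rule passing in each fit. It was 0 in limma with the clock covariate, with 311 at an unadjusted p under 0.05.

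In males the effect of the Kdm5 vectors depended on the AhR vector for 37 genes, 5 with a positive and 32 with a negative interaction. Bcl6 had an interaction of -4.05 ± 0.41 log2 (adjusted p = 4.4e-06) and Spata2l one of -1.73 ± 0.17. Pim3, Arrdc2, Tcim, Cep85l, Per1, Lgals4, Tmc7 and Herpud1 lay between -1.93 and -1.33, while Camk2b, Id2 and the pericentral factor Tbx3 lay at 2.00, 1.54 and 0.97. The male-biased genes had a positive interaction as a list (adjusted p = 0.00801; adjusted p = 0.77 with an estimated correlation). In females the interaction passed for 14 genes, 8 positive and 6 negative. Afp stood at -3.20 ± 0.41 (adjusted p = 0.00039), Tuba8 at -1.62, Rtn4rl1 at -1.27, Nfil3 at -1.26, and Mavs and Dpy19l1 at -0.68. Abcb1a, Srsf5, the thyroid hormone receptor gene Thrb, Ak4, Slc30a1 and Spata2l were positive, from 0.89 to 1.45. The female count was 1 and 23 without control mice 1 and 2, 9 without AhR mouse 1, 8 without Kdm5 mouse 1, and 1 without mouse 3 given both. The male count was 22 without control mouse 2 or 3, 7 without AhR mouse 3, 8, 24 and 19 without Kdm5 mice 1, 2 and 3, and 5 and 10 without mice 2 and 3 given both. Afp in females, 1 of 14 genes taken by the rule, and Bcl6, Id2 and Spata2l in males, 3 of 13, passed in each of 12 fits without 1 library. The male-biased genes had a negative interaction as a list in females (adjusted p = 0.0178; adjusted p = 0.74 with an estimated correlation).

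With control vectors, females and males differed at 976 of 2299 genes, 709 higher and 267 lower in females; the median gene was higher in females by 0.15 log2. With another scaling that median was 0.00 and 493 genes were higher and 487 lower, so that directions of modest differences depend on the scaling. The genes named here kept their direction with that scaling. Sult2a2 and Sult2a1 measured 148 ± 41.9 and 92.5 ± 45.6 FPKM in females and were listed at 0 in the 3 males. Cyp3a41a was higher in females by 9.66 ± 0.42 log2, Cyp2a4 by 8.79, Cyp2b13 by 7.72, Cyp2c69 by 7.38, Cyp2b9 by 7.27, Cyp2c40 by 6.93 and Slc22a26 by 6.14. Lower in females were Mup7 (-6.81 ± 0.58), Cyp4a12a (-6.47), Cyp4a12b (-6.25), Mup1 (-5.53), Mup14 (-5.22), Mup12 (-5.18), Mup20 (-4.74) and the fatty acid elongase gene Elovl3 (-4.60). All 22 female-biased genes were higher and 17 of 18 male-biased genes lower, with Ces2b higher at 0.65. Both lists passed with the preset and with an estimated correlation (adjusted p = 0.00115 and 0.0108).

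Bile acid genes differed in both directions, with 3 of 15 higher and 5 lower, among them Cyp7b1 at -3.01, Cyp8b1 at -2.39 and Cyp7a1 at -2.01. Of 6 genes of ethanol metabolism, Adh1 was higher (0.91) and Aldh1a1 (-0.97), Cyp2e1 (-0.53) and Cat (-0.46) were lower in females, and the list was lower (adjusted p = 0.0306; adjusted p = 0.38 with an estimated correlation). Of 22 genes of PPAR alpha and fatty acid oxidation, 3 were higher and 4 lower (adjusted p = 0.0492; adjusted p = 0.57 with an estimated correlation). Of 11 acute phase genes 9 were higher, such as Saa2 (2.00), Saa1 (1.62) and Saa3 (1.52). Of 7 interferon-stimulated genes 6 were higher, such as Gbp2 (1.72) and Irf7 (0.85), and of 7 cytokine and adhesion genes 4, such as Cxcl9 (1.73) and Icam1 (1.02). Of 9 macrophage markers 8 were higher, with Cd5l, C1qb and Vsig4 between 0.93 and 0.97, and of 7 quiescent stellate cell markers all 7, such as Rgs5 (0.72) and Reln (0.66). Of 5 p53 target genes 4 were higher, such as Bax (0.86) and Trp53inp1 (0.86). These lists of inflammation and cell types did not pass with an estimated correlation, with adjusted p of 0.44 for macrophages and for interferon-stimulated genes and 0.38 for quiescent stellate cells. Of 103 genes taken by the rule for this comparison 84 passed in each of 6 fits without 1 library; Cyp7a1 failed in 4, Saa1 and Saa3 in 1. The count of sex differences was 835 with the Kdm5 vectors, 902 with the AhR vector and 1131 with both.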

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

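The splits of libraries, the fits on the compared groups alone and the counts with 1 library left out were planned, and the tests of explanations for Afp, Bcl6 and the female excess were chosen after these had been seen; for microRNA-122 targets, progenitor markers and the clock score (Dbp minus Arntl) the bounds were set before those tests were run, and for the others after their results were seen.

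The difference between the sexes in the effect of the Kdm5 vectors passed for 40 genes, and in the effect of the AhR vector for 13; the interaction of both passed for 14 genes in females and 37 in males. For the Kdm5 vectors the differences (female minus male effect, log2) were 3.03 for Afp, 2.08 for Hspa1b, 1.48 for Onecut1, 1.47 for Tsc22d1, 1.47 for Tuba8, 1.39 for Irs2, 1.23 for Lad1, 1.19 for Gpr137, 1.19 for Tbc1d30 and 1.18 for Paqr9. They were -0.94 for Rgn, -1.18 for Srsf5, -1.18 for Abcb1a, -1.21 for Rhobtb1, -1.26 for Klf13, -1.27 for Slc38a2, -1.39 for Herpud1, -1.57 for Ppargc1a, -1.75 for Cyp3a44, -2.13 for Il1r1 and -3.66 for Lpin1. For the AhR vector they were 3.99 for Afp, -1.20 for Cd74, -1.33 for Rasgef1b, -1.34 for Herpud1, -1.39 for Kcnk5, -1.43 for H2-Ab1, -1.48 for Spata2l, -1.52 for H2-Aa, -1.61 for Arrdc2 and -1.92 for Bcl6. Of 100 splits of the vector labels within each sex, with the real one always included, 4 gave at least 40 genes for the Kdm5 vectors, with 112 the highest other, a share of 0.04 that is under 0.05 only as a single unadjusted test. That count was 1 without female control mouse 1, 2 without male control mouse 3 or male Kdm5 mouse 3, and 1 to 67 over all libraries left out in turn, so chance is not firmly excluded. For the AhR vector 6 of 100 gave at least 13, with 53 the highest other, and chance is not excluded. For the interaction, 8 of 100 gave at least 14 in females, with 195 the highest other, so chance is not excluded. In males 1 of 100 gave at least 37, with 6 the highest other. That 1 is the real split, so 0.01 is the smallest share that 100 splits can give, again unadjusted. The male count was 5 to 44 over all libraries left out in turn, so chance is not firmly excluded there. The splits move libraries between groups whose vector effects may be real. They therefore test against no vector effect at all, not against equal effects or no interaction. Splits with several times the real count, as with 112, 53 and 195, can hold real vector effects, and their cause was not tested.

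Afp was higher in all 9 females given an active vector (5.85 to 25.2 FPKM) than in any of the other 15 libraries (at most 1.01 FPKM). Male libraries do not set the usual level of Afp in females, so this cannot tell whether the female control mice were merely low. The same control mice serve every female comparison with control vectors, and that explanation is not excluded. A loss of microRNA-122 activity through competing hairpins may raise fetal genes, but only 4 listed targets (Aldoa, Ccng1, Klf6, Iqgap1) were tested. Their median log2 changes in females were -0.0629 under the Kdm5 vectors, 0.0665 under the AhR vector and 0.206 under both. Control mice also received hairpin vectors in both injections, and males given the same active vectors stayed at or below 1.01 FPKM. These values argue against a competition common to all hairpins and both sexes. Competition particular to single hairpins or to females stays open, and so few targets cannot decide it. Immature biliary cells cannot be decided either, since only 2 markers (Sox9, Cdh1) were tested. They gave medians of -0.0503, 0.0831 and 0.0745 in that order. An effect of the vectors that differs by sex remains open and was tested only as the difference itself.

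In males Bcl6 and the clock gene Dbp both changed with the vectors but parted in the group given both sets. Over controls, the Kdm5 vectors alone, the AhR vector alone and both sets, Bcl6 averaged 4.39, 7.84, 25.9 and 2.09 FPKM. Dbp averaged 7.53, 12.6, 18.9 and 32.0 FPKM in the same order, so both rose up to the AhR vector alone. With the clock score as covariate the change of Bcl6 under the AhR vector was 2.61 ± 0.40 log2 (adjusted p = 0.00721). Without it the change was 2.38 ± 0.29. A linear score of Dbp and Arntl thus did not account for that change. Its slope rests on the spread within groups, and the score itself differs between groups. Clock phase at collection is therefore not excluded as the cause. A single change in glucocorticoid tone is not decided. When the Kdm5 vectors were added to the AhR vector, 2 of 16 listed target genes rose (Fkbp5 1.07, Mt1 1.13). Another 7 fell, such as Ddit4 (-1.83) and Sgk1 (-0.77). The bound of at least 2 risen targets was set after these values were seen, and Fkbp5 failed in 5 of 6 fits without 1 library. The clock genes stay open as well. Their score averaged -0.22 in male controls and 1.52 in males given both sets of vectors, and no collection time is given. Time of collection, feeding, and a vector effect on the clock therefore remain open for those genes, and time of collection and feeding for Bcl6. They were not tested for the other genes either. With the clock score as covariate the count fell from 266 to 9 for both together in females. It fell from 25 to 2 for the AhR vector in males. The count for the Kdm5 vectors in females went from 158 to 169, and for their addition to the AhR vector in males from 75 to 71.

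The Kdm5 vectors changed 158 genes in females and 28 in males with the spread taken from all 24 libraries, but 1 in females and 19 in males when only the compared groups were fitted, and 169 and 0 with the clock score as covariate (203 male genes at an unadjusted p under 0.05 in limma), so that the excess in females depends on the setting. A choice of the table's genes by the female comparison is not decided, since 35.9% of genes had a p over 0.5 in it, against 26.5% to 44.7% in the other vector comparisons of 3 against 3 mice. A larger spread between male libraries was not seen, with a male to female ratio of median SDs of 0.86. The median SD over the control and Kdm5 groups was 0.169 in females and 0.145 in males. The main fit takes 1 spread per gene over both sexes, so it may understate the female spread. How far this raises the female count was not tested. Dependence on 1 female control library is not decided: without control mouse 1 the female count was 23, below the full male count of 28, and above 14, the highest male count without 1 library, a comparison chosen only after the first had been seen. That dependence, the choice of genes, the larger female spread, and a sex difference remain open.

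For comparisons of 3 against 3 mice, 10 splits exist, too few for a share under 0.05; in each the real count and the highest other are given. Under the Kdm5 vectors these were 158 and 90 in females and 28 and 0 in males. For the AhR vector they were 5 and 19 in females, where 4 splits, the real one included, gave at least 5, and 25 and 0 in males. For the AhR vector added to the Kdm5 vectors they were 48 and 0 in females and 21 and 0 in males, and for the Kdm5 vectors added to the AhR vector 16 and 1 in females and 75 and 0 in males. For both together they were 266 and 0 in females and 54 and 0 in males, and for the sexes with control vectors 976 and 0.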

How the results depend on the processing

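The stricter filter, the library weights, the pseudocounts 0.1 and 1 and the clock score (Dbp minus Arntl) were chosen after seeing the data. DESeq2, limma-voom and the edgeR count test were planned and not run, because the values are FPKM. No paired analysis was possible because the labels give every mouse its own number. Read depth is unknown and limits low genes most. The cause was not tested for the shifts between settings given here, except where the setting itself shows it.

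With median-of-ratios scaling the AhR vector changed 9 genes in females, with the stricter filter 1, and with pseudocount 1, 8. The stricter filter left Afp and Igf2 untested. Fits on the compared groups alone leave fewer residual degrees of freedom and take the spread from those groups only. In them the Kdm5 vectors changed 1 gene in females and 19 in males, all 19 higher. The fit of all libraries gave 158 and 28. On the compared groups the sex difference of the Kdm5 vectors held 15. There the AhR vector changed 1 in females and 9 in males, with a sex difference of 6. The AhR vector added to the Kdm5 vectors changed 0 in females (438 at an unadjusted p under 0.05) and 37 in males, and the Kdm5 vectors added to the AhR vector 0 in females (292) and 24 in males. Both together changed 21 in females and 30 in males, and the interaction held 1 in females and 13 in males.

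With library weights, the Kdm5 vectors changed 331 genes in females and 66 in males (sex difference 145), and the AhR vector 59 in males (sex difference 23). The AhR vector added to the Kdm5 vectors changed 235 in males, the reverse addition 37 in females and 179 in males, both together 594 in females and 113 in males, and the male interaction held 97. Averaged over both settings of the other vector, the Kdm5 vectors changed 51 genes in males, 26 higher and 25 lower (sex difference 122), and the AhR vector 78 in females and 52 in males (sex difference 116).

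With the clock score as covariate, the Kdm5 vectors changed 0 genes in males in limma (203 at an unadjusted p under 0.05; sex difference 11), and the AhR vector 2 in females and 2 in males (sex difference 4). The AhR vector added to the Kdm5 vectors changed 0 in females (251) and 0 in males (311), the reverse addition 0 in females (246), both together 9 in females and 0 in males (213), and the female interaction held 8. The other counts moved by less than 1.5 times: the Kdm5 vectors changed 169 genes in females (147 of them among the 158), their addition to the AhR vector in males 71 (55 among the 75), the male interaction held 35 (31 among the 37), and the sexes differed at 763 (701 among the 976). With that covariate Per3 turned to -0.0377 in females given both and Dbp to -0.37 in males given both and to 0.19 between the sexes; Dbp is part of the score, which by its construction removes its change. Of 330 list tests, 21 passed with the preset correlation and 2 with an estimated one.

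Leaving out each library in turn gave 23 to 279 genes for the Kdm5 vectors in females, 0 to 14 in males and 1 to 67 for the sex difference. For the AhR vector it gave 3 to 12, 9 to 26 and 4 to 19. The AhR vector added to the Kdm5 vectors gave 0 to 95 in females and 0 to 14 in males, and the reverse addition 5 to 36 and 35 to 65. Both together gave 44 to 238 in females and 16 to 42 in males, the interaction 1 to 23 and 5 to 44, and the sexes with control vectors 779 to 1042. Of 5776 alternative values of the named genes, 4303 kept direction and side of the threshold, 1469 lost the threshold (975 of them in 2652 values without 1 library), 1 gained it and 3 turned.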

Other observations

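The test of Wrnip1 and the averages over all mice were chosen after the data were seen.

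Over all mice, 12 with and 12 without the Kdm5 vectors, 120 genes passed in limma, 57 higher and 63 lower. Wrnip1 was the gene with the smallest adjusted p, at -0.43 ± 0.05 log2 (adjusted p = 0.000304). It lay between 9.99 and 13.9 FPKM with the vectors and between 13.3 and 17.9 FPKM without them, and was lower in all 4 pairs of groups. Also lower in all 4 pairs were Cldn1 (-0.38), a tight junction gene, Glyat (-0.30), Kyat3 (-0.52), Asap2 (-0.48) and Kdm5c itself (-0.31 ± 0.05, adjusted p = 0.00343). Higher in all 4 were Tacc2 (0.44), Tns1 (0.50), Garem1 (0.34), the corepressor gene Nab2 (0.56) and Acox2 (0.30), a peroxisomal oxidase of bile acid synthesis. Averaged within each sex, Kdm5c changed by -0.44 in males (limma adjusted p = 0.00215) and by -0.17 in females (adjusted p = 0.169). A fall in females is thus not established, and the difference between the sexes did not pass (adjusted p = 0.144).

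Over all mice, the AhR vector changed 12 genes, 5 higher and 7 lower. Arntl (-0.54 ± 0.09), Abcd4 (-0.35), Clpx (-0.41) and Cyp39a1 (-0.38) were lower and Dbp (1.32 ± 0.22) and Abhd2 (0.57) higher in all 4 pairs of groups. Cyp2b10 was lower by 1.39 on average, in 3 of 4 pairs.

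A hypothesis is that Wrnip1 responds to the Kdm5 vectors in both sexes, as a target of the demethylases or of a hairpin. Relabelling within the 4 pairs of groups gave an exact permutation p of 1.25e-05, two-sided, the smallest that 160000 relabelings can give. This is consistent with an effect of the vectors, but it may equally be an off-target effect of a hairpin, which nothing here separates, and the gene was picked as the leading one of 2299.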
